A study of Medicago truncatula with 12 samples.

How the data were processed

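Roots of the legume Medicago truncatula carrying a GUS RNAi construct (the control construct, aimed at a reporter gene the plant lacks) or a SKI3 RNAi construct were inoculated with water (mock) or with Sinorhizobium meliloti strain 1021, its nitrogen-fixing symbiont. Per the labels' protocols, 10 ml of a 1000-fold dilution of a culture at an optical density of 0.8 was applied, tissue was collected after 48 h and 30 µg of RNA entered each library. SKI3 is a subunit of the SUPERKILLER complex, which feeds messenger RNA to the cytoplasmic exosome for decay from the 3′ end. The transgenic roots were hairy roots raised with Agrobacterium rhizogenes. The labels give 3 biological replicates for each of the 4 groups, 12 libraries in all. The libraries were made with GMUCT 2.0, which captures the 5′ ends of uncapped polyadenylated RNA, that is, decay intermediates and the 3′ products of cleavage. A higher peak can therefore come from more cleavage, from slower removal of the product or from more of the transcript, and these values do not separate the possibilities.

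TopHat2, HOMER and DESeq2 are named in the submitters' processing notes, without versions. Peaks came from HOMER and were tested by the authors with DESeq2, per the file headers. The genome build and the annotation are not given in the sources used here. Coordinates are those of the deposited tables, and the chromosome of a peak was read from its gene identifier, since the peak tables have no chromosome or strand column. None of the gene identifiers matched the reference gene table (0 matches), so gene descriptions are those the authors deposited. The authors' assignment of a peak to a gene was kept also where the peak lies upstream or downstream of that gene. Such a peak need not come from the named transcript.

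Each of the 5 peak tables holds the authors' log2 fold change per peak. The authors also deposited the test score (a Wald statistic) and its p-value, which is unadjusted. Its mean column, headed as RPM, is treated here as a normalised signal of the authors with scaling set per comparison, since the SKI3 RNAi mock mean implied by the comparison of constructs was 1.72 ± 0.184 times (SD over 74 shared peaks) that implied by the inoculation of SKI3 RNAi roots, counting 3 libraries per group. Counting 2 SKI3 RNAi S. meliloti libraries the ratio was 1.56 with a narrower SD of 0.0407. Which libraries entered the authors' peak tests is not given in the sources used here. Only peaks with p at or under 0.05 are listed: the largest p was 0.0498, and each p equalled the normal tail of its statistic to within 6.05e-08. The number of peaks tested is not given in the sources used here, and the highest peak number was 16252. Standard errors printed for a peak are its log2 fold change divided by its statistic. The table of miRNA sites holds RPM values deposited by the authors for each of the 12 libraries in a window of 77 bases per site, and 4 p-values per site.

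The depth per library was recovered from the RPM values as the smallest whole read total that makes every site a whole number of reads (largest gap 2.27e-13 reads). The true total can be a multiple of it. On simulated data, 100% of 200 libraries with 44 sites gave back their total. An unequal-variance comparison of means returned the authors' p-values at all 26 sites with a value for the S. meliloti-inoculated comparison of constructs, all 38 for inoculation in GUS RNAi and all 29 for inoculation in SKI3 RNAi, within 0.001, when GUS RNAi S. meliloti library 1 and SKI3 RNAi S. meliloti library 2 were left out. With all libraries it returned 2, 18 and 9 of them. The authors' miRNA p-values thus rest on 2 libraries in each inoculated group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

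The design fixed before the data were examined asked for a count model if counts per library were at hand and otherwise for the split of the authors' lists, and the latter was used because the peak tables hold no values per library. Higher and lower peaks were compared with an exact two-sided binomial test against an even split, which treats peaks as independent, and again on genes, where a gene counts only if all its listed peaks go one way. Peaks of the same libraries share their depth and scaling. The binomial p therefore does not measure the spread between libraries and is no test of a construct or inoculation over replicates. Shared peaks were matched by peak identifier, and their directions compared with Fisher's exact test. For 12 gene lists fixed before the data were examined (symbiosis, miRNA target families, translation, RNA decay and RNA binding, defence and stress, cell wall, hormone, transport, nitrogen and carbon metabolism, chromatin, green tissue, and transcripts of other sources), the direction of members was compared with that of the other listed genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 49 tests. Words of at most 4 letters had to match as whole words, longer ones at the start of a word. On simulated lists of 20 genes drawn from the 225 genes of the mock comparison of constructs, 90.0% of reversed lists and 2.00% of the others were called over 100 simulated comparisons. These were adjusted over 12 tests, whereas the fixed lists held at most 15 listed genes and were adjusted over 49. The simulation therefore does not give the power of the fixed lists, and a short list that did not pass is no evidence of no difference. The authors' functional categories (83 tests, spellings merged) and 5 families picked after the data were seen were tested in the same way and are adjusted as separate families. Sites with a mean of at least 5 RPM over the 10 libraries other than those left out are called covered. They were compared on log2(RPM + 1) with exact permutation tests, which for 3 against 3 cannot go below 0.1.

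Genes are named first by a rule fixed beforehand, from which the text takes a part: per comparison, the 10 with the highest and the 10 with the lowest log2 fold change, members of the symbiosis and RNA decay lists, genes listed in opposite directions in a pair of comparisons, and miRNA targets with a listed peak. Other genes of the fixed lists and categories given as examples, the peaks named as lower in both comparisons of constructs, and the covered miRNA sites beside the strongest were chosen after their values were seen. Alternatives were a p limit of 0.01, an absolute log2 fold change of at least 2, genes in place of peaks, peaks inside genes, and peaks above the list's median signal. The Fisher's exact test of peaks above that median against the others was not fixed beforehand. The SKI3 transcript itself was not analysed here, so the knock-down is not checked by these values. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.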

Results

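Decay and cleavage intermediates were mapped in roots of 4 groups, GUS RNAi or SKI3 RNAi with mock or S. meliloti inoculation, with 3 libraries in each. Library depth as recovered from the RPM values was uneven. GUS RNAi mock libraries held 502650, 270486 and 804071 reads, and SKI3 RNAi mock libraries 52299, 416483 and 728289. Among GUS RNAi S. meliloti libraries the totals were 14369, 434006 and 305013. SKI3 RNAi S. meliloti libraries 1 and 3 held 260966 and 338650 reads, while library 2 was listed at 0 at all 44 miRNA sites and has no recoverable total. The 5 lists of changed peaks together held 764 distinct peaks assigned to 673 genes. Their p-values are unadjusted, and at a p limit of 0.05 chance alone would list 813 of 16252 peak numbers if all were tested, more than any list holds.

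**Figure D1:**
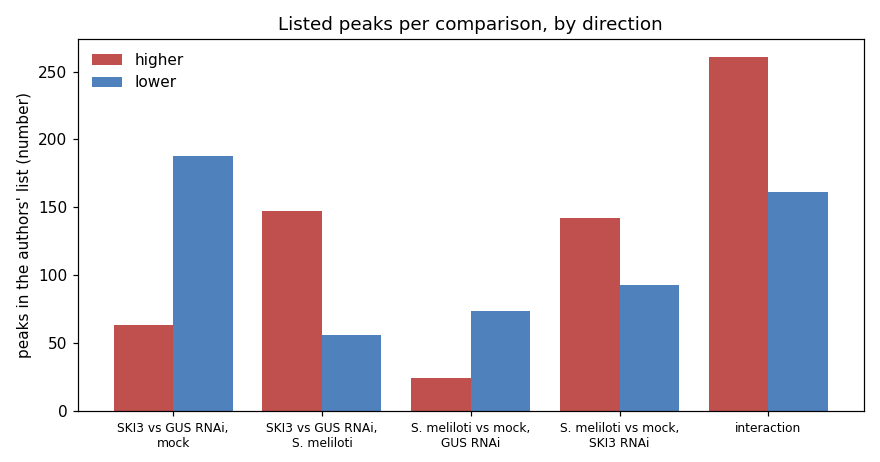
Number of listed peaks (vertical axis) higher and lower in each of the 5 comparisons of the authors' deposited table. Lower peaks outnumber higher ones for SKI3 RNAi in mock roots (188 against 63) and for S. meliloti in GUS RNAi roots (74 against 24), and the reverse holds in the other 3.

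The first question was what SKI3 RNAi changes in mock-inoculated roots. Most listed peaks were lower in SKI3 RNAi: 188 of 251, against 63 higher (exact binomial p = 1.25e-15), in 162 of 225 genes. Direction followed signal, with 16 higher and 109 lower above the list's median signal and 47 and 79 at or below it (Fisher's exact p = 9.40e-06). The tests of lists and categories below take no account of this. All 15 members of the fixed cell wall list were lower, although even this most extreme split did not pass adjustment against the other listed genes (Fisher's exact p = 0.0134, adjusted p = 0.327). They included extensins, structural glycoproteins of the wall: in the authors' deposited table the log2 fold change was -1.58 at Medtr4g065113, -1.53 at Medtr4g029550, -1.63 at Medtr4g029620 and -2.41 at the LRR extensin Medtr8g103700. Fasciclin-like arabinogalactan proteins, which sit at the cell surface, had log2 fold changes of -1.39 (Medtr2g090765), -2.91 (Medtr3g460780), -2.03 (Medtr5g098420) and -3.06 (Medtr7g106760) in the authors' deposited table. Outside the fixed words, 13 peaks in 7 genes of the pollen Ole e I family were all lower, with signals from 30.4 to 6986 in the authors' deposited table, a group chosen after its values were seen. The authors' cell wall category was lower in all 16 genes and their senescence category in all 12, neither past adjustment (Fisher's exact adjusted p = 0.0742 and 0.182). The category with the smallest adjusted p in this comparison, redox processes, went the other way, with 7 of 10 genes higher (Fisher's exact adjusted p = 0.0696).

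Peaks on the unanchored scaffolds 0052 and 0055 were also all lower in SKI3 RNAi mock roots (33 of 33, in 18 genes), a group chosen after its values were seen, so that a test of its direction on the same list would not be independent evidence. Of these, 22 lie at genes described as senescence-associated proteins. The smallest p in this comparison belonged to Medtr0055s0050, at bases 17122 to 17366 of scaffold 0055, with log2 fold change -3.21 (p = 2.35e-07) in the authors' deposited table. Medtr0052s0110, described as an rRNA intron-encoded homing endonuclease, had -1.53 in the authors' deposited table.

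Among single genes with the highest log2 fold changes, the authors' deposited table has Medtr5g004670 (hypothetical protein) at 6.42 with standard error 1.54 and p = 3.05e-05. Other genes at the top of the authors' deposited table were galactose oxidase Medtr1g055135 at 5.36, the F-box gene Medtr1g097330 at 4.63, clathrin light chain Medtr2g013220 at 4.53, cyclin p4 Medtr7g094880 at 4.40 and the RNA recognition motif gene Medtr3g082650 at 4.36. At the lower end of the authors' deposited table were VPS35A Medtr1g025610, a subunit of the retromer that recycles vacuolar sorting receptors, at -4.42, RSH2 Medtr8g020880 at -4.37, exocyst subunit Medtr8g021330 at -4.35 and the xyloglucan endotransglucosylase/hydrolase Medtr1g105495 at -4.27. All 26 peaks beyond an absolute log2 fold change of 4 had a signal under 10. The RNA decay and RNA binding list had 4 lower and 1 higher gene, among them helicases Medtr7g076820 (-3.22) and Medtr8g080240 (-3.22) in the authors' deposited table. In the symbiosis list, MtN21-like transporter Medtr3g072500 stood at 2.41 and nodulin-like Medtr4g082830 at -2.23 in the authors' deposited table. Hormone genes were the cytokinin receptor kinase Medtr1g013360 (-3.32), the AUX/IAA gene Medtr4g011880 (-3.85) and auxin response factor 2 Medtr8g100050 (-1.82) in the authors' deposited table. Adjusted over all peak numbers, 2 of the 251 peaks remained past 0.05, so most single genes named here rest on unadjusted p-values.

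In S. meliloti-inoculated roots, the groups that hold the library of 14369 reads and the library at 0, the balance was the other way. Of 203 listed peaks, 147 were higher and 56 lower in SKI3 RNAi (exact binomial p = 1.31e-10), in 124 and 45 genes. The authors' cell wall category was higher in all 6 genes and their senescence category in 8 of 10, with both directions in the other 2, neither past adjustment (Fisher's exact adjusted p = 0.839 and 0.512). The fixed cell wall list had 2 higher genes and 1 lower. Some senescence genes had near-equal values, so they may not be independent, as the tests take them to be. Peaks at Medtr0052s0100, Medtr0055s0090 and Medtr0055s0120 had 1.08, 1.06 and 1.06 with signals from 5533 to 5630 in the authors' deposited table. Chromatin genes (4 of 4), defence and stress genes (5 of 5) and transport genes (4 of 4) of the fixed lists were listed as higher, none past adjustment (adjusted p = 1.00 for each list). With all members higher already, lists this short could not have passed in that direction. Linker histone Medtr4g084700 had a log2 fold change of 1.83, core histone Medtr4g064983 1.69 and the histone methyltransferase ATXR3 gene Medtr4g045743 5.85 in the authors' deposited table. Peroxidases Medtr2g040000 (2.03) and Medtr5g022870 (4.76), Kunitz inhibitor Medtr2g073010 (1.71) and nitrate transporter Medtr8g069775 (1.57) were higher in the authors' deposited table. Ribosomal protein peaks were higher at Medtr2g101900 (L37-1, 1.83), Medtr3g108280 (P0-1, 2.02) and Medtr8g079485 (L38A, 4.56) in the authors' deposited table. The highest log2 fold changes of the authors' deposited table were 6.38 at Medtr4g119920 (hypothetical protein), 5.96 at anion transporter 4 Medtr4g030900, 5.92 at F-box/LRR gene Medtr1g050478 and 5.89 at ankyrin gene Medtr2g023440. The peaks at Medtr4g030900, Medtr2g023440 and peroxidase Medtr5g022870 lie upstream of the gene and that at Medtr1g050478 downstream. In this list 32 peaks lay upstream and 14 downstream of their gene. Of the 43 peaks beyond an absolute log2 fold change of 4 in this comparison, higher or lower, 42 had a signal under 10.

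On the lower side in inoculated roots stood both listed markers of green tissue, HCF173 Medtr4g005070 at -6.01 and photosystem II protein D Medtr4g073360 at -5.71 in the authors' deposited table (list adjusted p = 0.854). Both peaks lie upstream of their gene, as does the next one named, at Medtr2g014040. Late embryogenesis abundant gene Medtr2g014040 had -5.65, leucoanthocyanidin dioxygenase Medtr5g011250 -5.19, phosphoinositide phosphatase SAC4 Medtr8g022740 -5.17 and pectinesterase Medtr7g108900 -5.03 in the authors' deposited table. Genes of the authors' metabolism category were lower more often than the rest (14 of 24 genes, Fisher's exact adjusted p = 0.0191 over 83 category tests). Direction followed signal in this list, with 89 higher and 12 lower above its median and 58 and 44 at or below it. The category test takes no account of this. RNA decay and RNA binding genes went both ways, with helicase Medtr1g026830 (peak downstream of the gene) at 2.03 and helicase Medtr2g438110 at -2.34 in the authors' deposited table. With an absolute log2 fold change of at least 2 the split was no longer uneven (43.7% lower, exact binomial p = 0.237). No peak remained after adjustment over all peak numbers (0 of 203).

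Mock and inoculated lists for SKI3 RNAi shared 19 peaks, 5 in the same direction and 14 lower in mock but higher in inoculated roots. Since every shared peak was lower in mock roots, Fisher's exact test of direction could not separate them (p = 1.00). The 14 included Ole e I genes Medtr1g033080 (-1.08 in mock, 0.86 inoculated), Medtr1g033100 (-1.18 and 1.00), Medtr1g033130 (-1.46 and 0.95) and Medtr4g088735 (-1.26 and 1.09) in the authors' deposited table. Extensin Medtr4g065113 (-1.58 and 0.90) and senescence-associated Medtr0052s0150 (-2.04 and 1.57) behaved likewise in the authors' deposited table. Lower in both were single peaks at the hypothetical proteins Medtr3g035650 (-1.43 and -1.55), Medtr0021s0130 (-3.07 and -2.51) and Medtr0055s0030 (-2.26 and -1.86) of the authors' deposited table. The other peaks lower in both lie at senescence-associated Medtr0052s0070 (-2.30 and -2.36) and Medtr0055s0090 (-2.48 and -1.75) in the authors' deposited table. Medtr0055s0090 also holds 1 of the 14 peaks of opposite direction (-1.64 and 1.38 in the authors' deposited table). Other peaks were higher in inoculated roots at Medtr3g035650 (2.78) and Medtr0055s0030 (1.27 and 3.36) in the authors' deposited table. Medtr0052s0070 had further peaks both ways there (1.18, 2.86 and -4.84 in the authors' deposited table). These genes were therefore not lower throughout.

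Inoculation of GUS RNAi roots, the response of the control roots to the symbiont, gave the shortest list. It held 98 peaks, 24 higher and 74 lower with S. meliloti (exact binomial p = 4.22e-07), in 96 genes. Signals were low: 70 of the 98 peaks had a signal under 10, and none remained after adjustment over all peak numbers (smallest p 0.00342). All 48 peaks beyond an absolute log2 fold change of 4 had a signal under 10. The inoculated group holds the library of 14369 reads, in which 1 read is worth 69.6 RPM. Whether low depth lowered peaks of this list was not tested. Higher values in the authors' deposited table were cytochrome P450 Medtr4g104610 at 5.35, prolyl 4-hydroxylase Medtr1g116810 at 5.19, MIP-family channel Medtr6g069040 at 5.05, bHLH93-like factor Medtr7g076840 at 5.01, the 30S ribosomal protein S13 gene Medtr3g073140 at 4.90 and cytokinin oxidase Medtr4g126160, of an enzyme family that degrades cytokinins, at 4.16. Lower values in the authors' deposited table were F-box gene Medtr3g111170 at -5.66, bZIP factor Medtr4g073100 at -5.23, ankyrin gene Medtr2g023440 at -5.20, splicing factor Medtr8g009970 at -5.15, the ENTH domain gene Medtr7g072310 at -4.91, synaptobrevin Medtr1g111890 at -4.69 and RING finger gene Medtr1g074190 at -4.67. WRKY factors Medtr4g082580 (-1.55) and Medtr7g011820 (-4.23), ribosomal proteins Medtr2g012450 (-4.58) and Medtr1g044130 (-2.94), and RNA-binding genes Medtr1g026830 (-1.62) and Medtr7g094660 (-4.39) were lower in the authors' deposited table. Of the peaks named for this list, those at Medtr3g111170 and Medtr2g023440 lie upstream of the gene. Those at Medtr6g069040, Medtr7g076840 and Medtr1g026830 lie downstream. No fixed list passed adjustment for direction against the rest (adjusted p = 1.00 for each list with a listed gene). Each held at most 5 listed genes, so this is no evidence of no difference.

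In SKI3 RNAi roots inoculation gave 235 peaks, 142 higher and 93 lower (exact binomial p = 0.00168). The inoculated group holds the library listed at 0 at all miRNA sites. Higher peaks prevailed only above the list's median signal, with 97 higher and 20 lower, against 45 higher and 73 lower at or below it (Fisher's exact p = 1.44e-12). On genes the split was 110 higher to 91 lower (exact binomial p = 0.204), and without the peaks of scaffolds 0052 and 0055 47.7% were lower (exact binomial p = 0.567). With an absolute log2 fold change of at least 2 the direction turned, with 51.5% lower (exact binomial p = 0.756). All 29 peaks of the authors' senescence category were higher with S. meliloti (Fisher's exact adjusted p = 0.0191), in a test that counts genes with near-equal values as independent. All 16 of the cell wall category, in 12 genes, were higher too (adjusted p = 0.0191). Each had a signal of at least 11.3, above the list's median of 9.48, where higher peaks prevailed anyway. That test therefore does not separate the category from signal. Both categories were lower throughout in the mock comparison of constructs, which shares the SKI3 RNAi mock libraries. Their directions here are therefore not independent of that comparison. The 8 genes of the fixed cell wall list were also higher (adjusted p = 0.327). Extensins Medtr4g065113 (1.80), Medtr6g034870 (1.09) and Medtr6g034920 (1.17) and arabinogalactan proteins Medtr2g090765 (1.92) and Medtr7g106760 (3.35) were among them in the authors' deposited table. Nodule cysteine-rich peptide Medtr7g021640, of a family made in nodules, had 1.82 in the authors' deposited table. Further genes listed as higher in the authors' deposited table were S-locus lectin kinase Medtr8g465980 at 4.94, peter Pan-like Medtr4g075050 at 4.92, knotted-like homeobox Medtr1g012960 at 4.45 (p = 0.000944), amino acid transporter Medtr7g007850 at 4.24 and abscisic acid receptor Medtr5g030500 at 2.20. Genes listed as lower in the authors' deposited table were Medtr2g014040 at -5.72, YUCCA10-like Medtr4g051642, of the auxin biosynthesis enzymes, at -5.31, acid phosphatase Medtr6g090070 at -5.02, GDP-mannose epimerase Medtr7g115080 at -5.02, acyl-CoA synthetase Medtr0161s0050 at -4.99, sucrose transporter 2 Medtr8g468330 at -4.51 and elongation factor Medtr8g014960 at -4.23. Of the RNA decay and RNA binding list, Medtr4g052940 (2.05) and Medtr6g004810 (1.78) were higher and helicase BRM Medtr7g078090 (-3.77) and Medtr7g117495 (-4.51) lower in the authors' deposited table. Medtr7g078090 is in that list by the word helicase alone. All 73 peaks of this comparison beyond an absolute log2 fold change of 4 had a signal under 10.

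The GUS RNAi and SKI3 RNAi lists for inoculation shared 3 peaks. Of these, 2 went in opposite directions, both at Ole e I gene Medtr1g116947 on chromosome 1 (bases 52818817 to 52820030 and 52820854 to 52822118), with log2 fold changes of -1.03 and -1.09 in GUS RNAi and 1.47 and 1.64 in SKI3 RNAi in the authors' deposited table. Lists that share libraries also share peaks, with directions built in by the shared group. The SKI3 mock lists shared 74 peaks, all 74 opposite, the SKI3 S. meliloti lists 64 (63 the same way), the GUS S. meliloti lists 18 (all 18 opposite) and the GUS mock lists 12 (11 the same way).

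**Figure D2:**
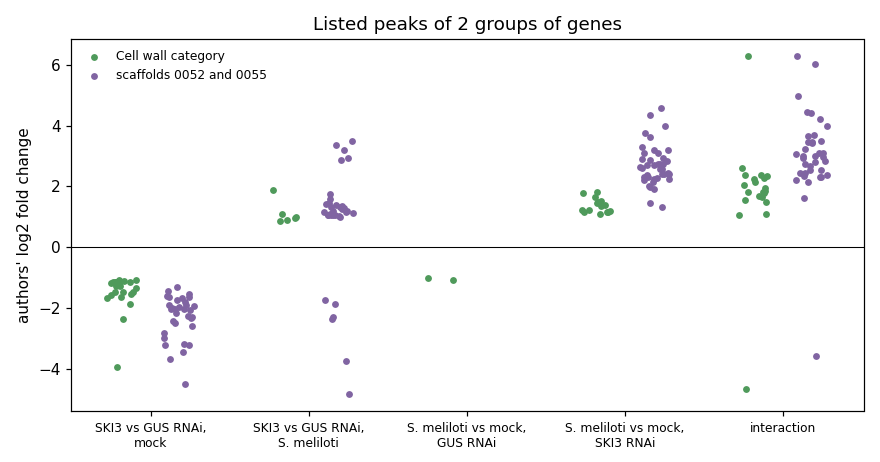
Log2 fold change of the authors' deposited table (vertical axis) for each listed peak of the cell wall category and of scaffolds 0052 and 0055, by comparison (horizontal axis); each point is 1 peak. The 22 cell wall peaks lie below 0 for SKI3 RNAi in mock roots and the 16 for S. meliloti in SKI3 RNAi roots above it.

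The interaction list asks whether inoculation changes a peak differently under SKI3 RNAi. It was the longest, with 422 peaks, 261 higher and 161 lower (exact binomial p = 1.29e-06), in 230 and 154 genes. Above the list's median signal 162 were higher and 49 lower, whereas at or below it 99 were higher and 112 lower (Fisher's exact p = 3.54e-10). Of its peaks 274 were in at least 1 of the other lists, all in the direction that list implies. The authors' cell wall category was higher in 15 of 16 genes (Fisher's exact adjusted p = 0.0487) and the senescence category in all 12 (adjusted p = 0.0449), while metabolism was lower in 25 of 40 (adjusted p = 0.0487). These tests take no account of signal, which direction followed in this list. They also count the senescence genes as independent, although some had near-equal values in inoculated roots. The interaction shares its libraries with the other lists, so these directions are not independent of theirs. Expansin A10 Medtr5g011210, which loosens cell walls, stood at 6.29, the xyloglucan enzyme Medtr1g105495 at 4.31 and extensin Medtr4g065113 at 2.35, whereas xyloglucan glycosyltransferase Medtr3g103500 had -5.23 in the authors' deposited table. The fixed cell wall list was higher in 13 of 15 genes (adjusted p = 0.536). Among the highest log2 fold changes of the authors' deposited table were anion transporter 4 Medtr4g030900 at 7.52, the CLE peptide gene MtCLE05 Medtr1g100733 at 7.20, splicing factor Medtr8g009970 at 7.19, elongation factor Medtr4g101740 at 6.78 and ankyrin gene Medtr2g023440 at 6.58. Among the lowest of the authors' deposited table were cyclin p4 Medtr7g094880 at -8.38, cyclin-dependent kinase Medtr5g026960 at -7.58, NADH dehydrogenase Medtr2g036340 at -7.48, Medtr2g014040 at -6.54 (p = 0.000304), MIP-family channel Medtr6g069040 at -6.51 and COP9 subunit Medtr7g087530 at -6.18. Green tissue markers were lower at Medtr1g110440 (-5.87), Medtr4g005070 (-5.61) and Medtr4g073360 (-5.27) and higher at Medtr2g081090 (5.19) in the authors' deposited table. Of the other fixed lists, translation was higher in 8 of 13 genes, defence and stress in 7 of 12, transport in 5 of 12, chromatin in 5 of 6, hormone in 2 of 2, miRNA target families in 1 of 2, nitrogen and carbon metabolism in 1 of 1 and transcripts of other sources in 1 of 2. None of the 49 list tests over the 5 comparisons passed adjustment (smallest Fisher's exact adjusted p = 0.327). Some members match a list by a word alone: Medtr5g013690, an S-ribonuclease-binding protein, counts under both miRNA target families and RNA decay. Likewise Medtr7g078090, described as ATP-dependent helicase BRM, counts under RNA decay by the word helicase. RNA decay and RNA binding genes split evenly, 5 higher and 5 lower, and nodulin-like Medtr4g082830 had 3.37 in the authors' deposited table. Of 192 peaks beyond an absolute log2 fold change of 4, 185 had a signal under 10, and 2 of the 422 remained after adjustment over all peak numbers.

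Cleavage at miRNA target sites was listed for 44 sites in 39 genes, of 21 miRNA families. Reads were few, and 14 sites in 12 genes were covered. The strongest site was the miR393b site of Medtr7g083610, a TIR1-like auxin receptor, on the minus strand of chromosome 7 at bases 32173993 to 32174069. Its level was 570 ± 3.03 RPM (SD, n = 3) in GUS RNAi mock roots and 294 ± 15.5 RPM (SD, n = 3) in SKI3 RNAi mock roots. This is a log2 difference of -0.95 with no overlap between libraries, which chance gives for 10% of sites, at the smallest p that 3 against 3 allows (exact permutation p = 0.1). The authors' unadjusted p for this site was 0.000713 in this comparison, 0.167 for the constructs in inoculated roots, 0.344 for inoculation in GUS RNAi roots and 0.0426 for inoculation in SKI3 RNAi roots. In inoculated roots GUS RNAi libraries had 487, 415 and 531 RPM and SKI3 RNAi libraries 261, 0 and 254. The same gene holds a listed peak over the site, lower in SKI3 RNAi mock roots (-0.89, p = 0.0196), and Medtr8g083140 with a miR2673a site holds another in the interaction list (1.40, p = 0.0131), both in the authors' deposited table. No other of the 39 target genes had a listed peak.

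**Figure D3:**
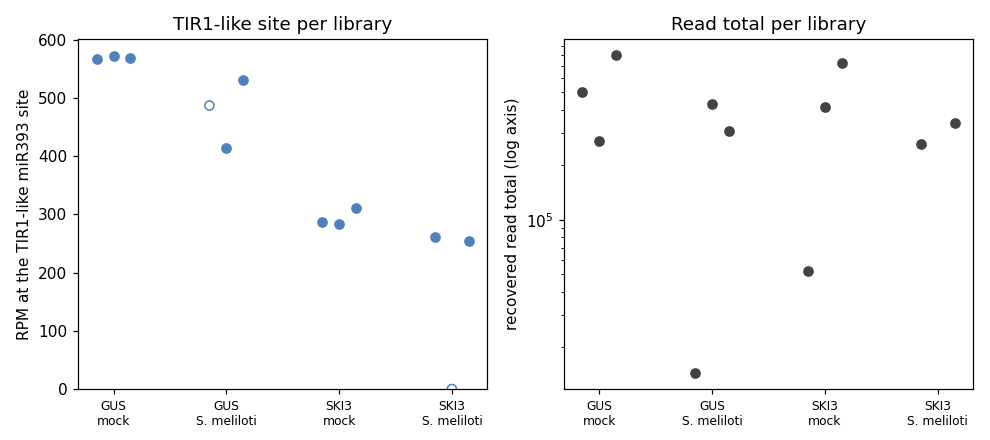
Left, RPM at the TIR1-like miR393 site (vertical axis) for each library of the 4 groups, with open circles for the 2 libraries the authors' miRNA p-values leave out. Right, recovered read total per library on a log axis, from 14369 to 804071. In mock roots the SKI3 RNAi libraries (294 RPM on average) lie below the GUS RNAi ones (570).

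At most other covered sites the constructs differed in mock roots by less than the spread between libraries. The miR172b site of AP2-like Medtr2g093060, of a family of flowering and nodulation regulators, had 59.1 ± 4.10 RPM (SD, n = 3) in GUS RNAi and 61.9 ± 23.4 RPM (SD, n = 3) in SKI3 RNAi. At the miR160c site of auxin response factor Medtr2g094570 the levels were 86.7 ± 26.8 and 79.7 ± 16.6 RPM (SD, n = 3 each). The miR156e site of squamosa promoter-binding-like Medtr5g046670 had 55.4 ± 29.0 and 80.2 ± 46.6 RPM (SD, n = 3 each), and the miR2111c site of kelch-repeat Medtr7g029290 had 58.2 ± 35.0 and 34.3 ± 13.6 RPM (SD, n = 3 each). At the second miR172b gene, Medtr4g061200, levels were 23.6 ± 1.36 and 11.2 ± 7.29 RPM (SD, n = 3 each), also without overlap (exact permutation p = 0.1). A single read was worth 19.1 RPM in SKI3 RNAi mock library 1, against 2.40 and 1.37 RPM in libraries 2 and 3 of that group.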

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

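All tests in this part were chosen after the values had been seen. The interaction list holds 422 peaks at which the constructs differed in their response to S. meliloti by the authors' unadjusted p. Only 2 of these remained after adjustment over all peak numbers. A difference in direction was also seen between mock and inoculated roots at 14 peaks for SKI3 RNAi and at 2 peaks for inoculation in GUS RNAi against SKI3 RNAi roots. All of them are in the interaction list, which is no further evidence: the interaction is the difference of the paired log2 fold changes, to within 0.135 at these peaks, so opposite signs build it in.

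Peaks of scaffolds 0052 and 0055 were lower in SKI3 RNAi mock roots at all 33 listed peaks, with a median log2 fold change of -2.04. In inoculated roots 28 listed peaks of these scaffolds were higher in SKI3 RNAi and 6 lower, with both directions in 4 of 16 genes, and all 40 listed for S. meliloti in SKI3 RNAi roots were higher. The last of these comparisons shares the SKI3 RNAi mock libraries, in which the scaffolds were picked as lower. Of its 40 peaks, 25 are also in the mock list, all in the opposite direction. Their rise is therefore partly built in and is no further evidence. In mock roots 11 of the lower peaks carry no senescence annotation, but the scaffolds were picked for their direction, so this number is void as a test. Signal of the scaffolds as linked sequence (a homing endonuclease of rRNA introns lies on scaffold 0052) and a change of the senescence-annotated genes alone therefore cannot be told apart, and neither can library scaling: listed abundant peaks elsewhere had a median of -1.43, but all are listed for their p, and peaks that did not pass are not analysed here. A difference between the constructs stays open as well.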

How the results depend on the processing

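Adjustment over peak numbers, a log2 fold limit of 1 and the removal of scaffolds 0052 and 0055 were added after seeing the data, as were all settings for the TIR1-like site; the others were set before the data were examined. Comparisons are given in the order SKI3 RNAi in mock roots, SKI3 RNAi in inoculated roots, S. meliloti in GUS RNAi, S. meliloti in SKI3 RNAi, interaction. A p limit of 0.01 left 67, 40, 8, 57 and 88 peaks, and signal above the list's median, which shortens each list by construction, left 125, 101, 49, 117 and 211. An absolute log2 fold change of at least 2 left 155 and 103 in the first and second. Adjustment over peak numbers left 2, 0, 0, 4 and 2, where 100% of the first, 0% of the fourth and 0% of the last were lower, too few for a test. The share lower lost its call in the second (43.7%) and turned in the fourth (51.5%) at an absolute log2 fold change of at least 2, and lost its call in the fourth on genes (45.3%) and without the scaffolds (47.7%); the cause was not tested. The p limit of 0.01 left 2 shared peaks for SKI3 RNAi, 0 for S. meliloti, 86 interaction peaks in another list, and 0, 1, 29 and 9 for GUS mock, GUS S. meliloti, SKI3 mock and SKI3 S. meliloti libraries in common. The fold limit of 2 left 2 and 0 shared peaks. Counting families gave 21 for 44 miRNA sites, 1 site (the TIR1-like one) had an authors' p under 0.01 in mock roots, and 0 target genes kept a listed peak at 0.01. For the fixed lists only peaks in place of genes and the p limit of 0.01 were run, and neither called a list (0 in each).

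The TIR1-like difference of -0.95 was from -0.997 to -0.924 without replicates 1, 2 or 3. A replicate block cannot move it, as the groups are balanced. Over both inoculations it was -0.91 without the libraries in doubt and -2.25 with all. Same-numbered mock libraries had correlations of 0.077, 0.47 and 0.46 of their deviations over 14 sites. Those with different numbers ran from -0.56 to 0.091. GUS RNAi libraries 2 and 3 correlated best with their own number and GUS RNAi library 1 with another (0.091). Whether the numbers pair the libraries therefore stays open. No paired analysis was possible because the peak tables hold no values per library, and for the same reason other count tools, size factors, filters and leaving out replicates were not run for peaks. Matching within 50 bases on the same strand was not run, as the peak tables give no strand.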

Other observations

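All tests in this part were chosen after the values had been seen. The libraries differ widely in what they can show. In GUS RNAi S. meliloti library 1, 42 of 44 miRNA sites were listed at 0. At its 14369 reads, 100000 Poisson draws from the mean of the other libraries of its group gave 36 to 42 sites at 0 (central 95%), so low depth may account for the zeros, with the observed number at the edge of the range. For SKI3 RNAi S. meliloti library 2, with all 44 sites at 0, a total of 11661 reads would give 3 expected reads at the TIR1-like site; low depth and a column that was not filled cannot be told apart, since no total can be recovered.

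The TIR1-like miR393 site was lower in SKI3 RNAi roots in both inoculations, by -0.95 in mock roots and, from 2 libraries per group, by -0.87 in inoculated roots on the log2(RPM + 1) scale, and the hypothesis is a difference between the constructs. Dilution of the SKI3 RNAi libraries by other reads would lower all sites alike, but the other 11 covered target genes had a median log2 ratio of -0.088 (SD 0.68) in mock roots. That argues against dilution there, but weakly, since Medtr4g061200 among them had -1.20 and several of their sites held few reads. In inoculated roots it stays open: the same 11 genes, 8 of them lower, had a median log2 ratio of -0.46 (SD 0.93), within 1 SD of both 0 and the TIR1-like value, so dilution and a difference between the constructs cannot be told apart there. Counting error is too small in mock roots, where pooled reads (360 against 898) gave a ratio of 0.528 with a 95% exact interval from 0.466 to 0.598. The exact permutation test within inoculations, over 120 regroupings without the libraries in doubt, gave p = 0.0167, the smallest it can give, and 0.117 after adjustment over the 14 covered sites. A lone site could not get below 0.233 after adjustment, or 0.07 with all libraries, so this test is void for a single site. The miR172b site of Medtr4g061200 gave the same exact permutation p and adjusted p with a mean difference of -1.07, so the TIR1-like site does not stand alone in this test. The mean difference of the TIR1-like site over both inoculations was -0.91. With all libraries it was -2.25 (exact permutation p = 0.005, adjusted p = 0.07), where SKI3 RNAi S. meliloti library 2 enters at 0, and the miR172b difference was -0.91 (p = 0.335). In mock roots the authors' p adjusted over 40 sites was 0.0285. It rests on an SD of 3.03 RPM in GUS RNAi libraries, where counting alone gives 36.3 RPM at the recovered totals, and with counting as the least variance the adjusted p was 0.0691. A difference between the constructs in mock roots therefore stays open too, and whether it may reflect miR393 cleavage, removal of the cleaved product or the level of the transcript cannot be settled from these values.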
